A study of Bacillus subtilis subsp. subtilis str. 168 with 8 samples.

How the data were processed

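The data are 8 macroarrays, nylon membranes spotted with one feature per gene, that compare *Bacillus subtilis* 168 wild type with a *ccpN* mutant, 4 arrays per strain. Per the labels' protocols, cDNA was made from 2 µg of total RNA with a 33P label and hybridised to the membranes. Image quantification, and whether duplicate spots were averaged, are not given in the sources used here. Per the file headers, the deposited sample files hold raw values, and they were used as spot intensity on each array's own scale. The deposited value table holds a signal that, tested against the sample files, equals the raw value minus a background, divided by the array's mean, so that each array averages 1. That background was the same for all but 1 to 13 features per array and came to 2820 to 8643. The table's medians were 0.363, 0.453, 0.41 and 0.387 in wild-type arrays 1 to 4, and 0.407, 0.501, 0.41 and 0.361 in the mutant arrays. Its scale is linear, and which background spots or areas the authors used stays unknown.

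Groups were taken from the labels. The series design assigns 3 independent RNA extracts and membrane sets A, B and C to 4 experiments. It repeats the same sample names for experiments 2, 3 and 4, which was read as arrays 2, 3 and 4 of each strain. Experiments 3 and 4 share extract 3, so their arrays were averaged within a strain after normalization. Features were named through the platform annotation, of which 3862 had 1 gene symbol, 32 several and 213 none. Of these, 3848 were matched to the RefSeq gene table (assembly ASM904v1), which was used for current names and for which genes neighbour each other, and 14 kept the platform symbol. For list membership, 20 current symbols of renamed genes were added by hand after the data were opened, several of them by position among neighbouring genes. The 2 features of each of 13 genes were averaged, and they disagreed most for *ispA* (0.37 and -0.78). This left 4094 genes and features, with no filter on dim spots.

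Intensity was corrected with normexp (offset 50), quantile normalized between arrays and taken to log2. Levels are given relative to the median gene. The strains were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, strain as the term, 3 extracts per strain, 4 residual degrees of freedom) with Benjamini-Hochberg adjustment and a threshold of 0.05. Gene lists with at least 3 measured members, 27 of 28, were tested with camera at a preset correlation of 0.01, adjusted over the lists. The comparison, the 28 lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule names *ccpN*, *ppsR*, *gapB*, *speD*, *pckA*, *gapA* and *argR* in any case. It adds up to 10 genes per direction by size of change among those passing in the same direction in 3 of 3 extracts, filled to 5 by unadjusted p, and up to 4 members by p of each list called or holding a called gene. It gave 27 genes, and others are said to be chosen after their values were seen.

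The design states that the experiments were done on different days, so that the number marks a shared day and membrane set. Deviations from the strain means correlated at 0.46, 0.70 and 0.68 across genes for wild type and mutant of extracts 1, 2 and 3, and at -0.02 to -0.48 between different extracts. The numbers therefore pair the samples, and the fit with extract as a block (2 residual degrees of freedom) is given where it changes a call. The p-values rest on 3 RNA extracts per strain. Membrane set A carries extracts 1 and 2, and sets B and C carry extract 3; each set holds both strains.

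On simulated arrays for this comparison, with the spread between extracts taken from the data and 200 of 4094 genes changed, the fit without block recovered 0% of 2-fold, 22% of 4-fold and 73% of 8-fold changes with 0 false calls. The fit with block recovered 0%, 76.5% and 88%, with 0, 9 and 5 false calls. A planted shift of -0.6 in the overflow and acetoin list over the same genes was called, with 1 list called in all.

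Alternatives were the block, 4 arrays as replicates with and without blocks, each array of extract 3 alone, no background correction, other normalizations, no dim genes, an intensity trend, the value table (log2 with 0.05 added), leaving out extracts, an estimated correlation and fry. Chosen after the data were seen were a correction for array position, its combination with the block, the block without each extract, and gene groups by name. The position correction subtracts, per array, the median deviation of 14 features close in feature number, at distances that include 1, 7, 8, 9 and 16. Of the alternatives, those with 4 arrays treat the arrays of experiments 3 and 4 as separate samples, although they share extract 3. This overstates the replication. The exception is extract as a random block, which links those arrays within a strain. It does not pair wild type with mutant. Figures were drawn with matplotlib 3.10.9.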

Results

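Genome-wide transcript levels were measured in *Bacillus subtilis* 168, a Gram-positive soil bacterium, in the wild type and in a mutant of *ccpN*, earlier called *yqzB*. CcpN is a transcriptional repressor of gluconeogenic genes in cells fed with glucose. The mutation is described as non-polar, that is, made so as to spare the downstream gene. Both strains were grown in TSS minimal medium with 10 g/L glucose and collected in exponential growth at an OD600 of 0.5. Each of the 8 macroarrays, 4 per strain, was hybridised with radiolabelled cDNA made from 2 µg of total RNA and gave 1 intensity for each of 4107 features. The 4 experiments used 3 independent RNA extracts per strain, because experiments 3 and 4 shared extract 3 on different membrane sets. Arrays of one extract were averaged, so that n = 3 extracts per strain throughout. Median raw intensity was 30416 to 127771 per array, or 3.52 to 32.3 times the background implied by the deposited value table, and was lowest relative to background in the mutant array of extract 1. The small number of arrays limits the precision.

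The first question was whether the mutated gene and its operon partner were seen at altered levels. The *ccpN* feature lay 2.05 ± 0.24 (SD, n = 3) log2 units above the median gene in the wild type and 1.40 ± 0.26 (SD, n = 3) above it in the mutant. The difference of -0.65 ± 0.31 (SE) was in the same direction in 3 of 3 extracts, and did not pass the test (limma, adjusted p = 0.998). For extract 3 the log2 ratio was -0.81 in membrane set B and 0.04 in set C. *ppsR*, earlier *yqfL*, the downstream gene, differed by 0.06 ± 0.41 (SE, limma adjusted p = 0.998). Which part of *ccpN* was removed and which part the array feature covers are not given in the sources used here, so the *ccpN* signal is no check of the strain labels.

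The second question was how the genes that the repressor is known to control differed between the strains. *gapB*, the glyceraldehyde-3-phosphate dehydrogenase of gluconeogenesis, rose 24.9-fold in the mutant (log2 fold change 4.64 ± 0.32, SE, n = 3; limma adjusted p = 0.0028). The wild-type signal of *gapB* was 3.01 to 8.36 times background, and the log2 fold change was 3.91 without background correction and 3.93 on the deposited value table, so the fold depends on that step. *pckA*, which encodes phosphoenolpyruvate carboxykinase, rose 10.6-fold (3.41 ± 0.33, SE; limma adjusted p = 0.01). Within membrane set A the *gapB* ratios were 4.02 and 5 on the log2 scale, and they were 4.92 in set B and 4.85 in set C. Those of *pckA* were 2.84, 3.32, 3.94 and 4.2. *speD*, for the S-adenosylmethionine decarboxylase of polyamine synthesis, was 7.74-fold higher (2.95 ± 0.62, SE), with ratios of 2.74, 3.34 and 2.78 in the 3 extracts. Its level had an SD of 1.09 in the wild type and 0.77 in the mutant. It missed the threshold over all genes (limma adjusted p = 0.226) and passed it with RNA extract as a block (limma adjusted p = 0.00564). With the 4 arrays it missed it with extract as a random block (limma adjusted p = 0.0628) and with membrane set as a block (limma adjusted p = 0.0794). That random block links arrays of one extract within a strain and does not pair the strains. Its SE for *speD* was 0.57, near the 0.62 without a block, against 0.24 with extract as a fixed block. *speD* passed in 7 of 28 settings. Of these 3 CcpN targets 2 rose, and 3 rose when adjusted over the list alone. *gapB* and *speD* lie next to each other on the chromosome, so the 3 are not shown to be independent of each other. The list as a whole had a median log2 fold change of 3.41 (camera adjusted p = 6.87e-13). With an estimated correlation the call was lost (adjusted p = 0.0975). The gluconeogenesis list shares *gapB* and *pckA* with it and rose with the same median of 3.41 (camera adjusted p = 6.1e-08; adjusted p = 0.157 with an estimated correlation). Of its 3 measured members 2 rose, also when adjusted over the list alone, whereas *fbp*, the fructose-1,6-bisphosphatase gene, differed by 0.07 ± 0.31 (SE).

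**Figure D1:**
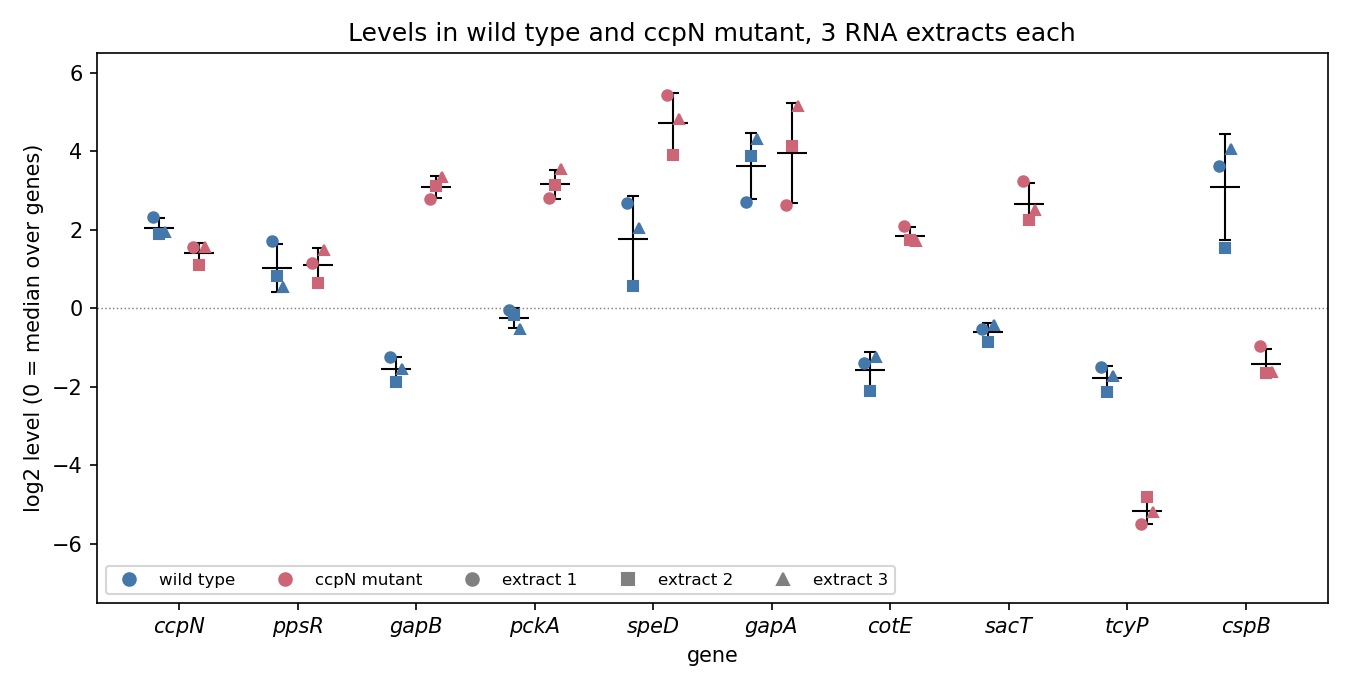
Log2 level (y axis, 0 is the median over genes) of 10 genes in wild type (blue) and *ccpN* mutant (red). Points are the 3 RNA extracts, by shape, and bars are the mean ± SD; *gapB* lies at -1.56 in the wild type and 3.08 in the mutant, and the *ccpN* and *gapA* points of the strains lie close together or overlap.

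Glycolysis, the breakdown of glucose, was examined next. None of the 13 measured genes passed the test over all genes or adjusted over the list alone in limma, and their median log2 fold change was -0.23 (camera adjusted p = 0.594). *gapA*, the glycolytic counterpart of *gapB*, differed by 0.33 ± 0.68 (SE; limma adjusted p = 0.998). *cggR*, which encodes the repressor at the head of the *gapA* operon and was singled out after its values were seen, lay at -1.75 ± 0.61 (SE). It missed the threshold without extract as a block (limma adjusted p = 0.862) and passed it with the block (limma adjusted p = 0.0363). It did not pass with a position correction and the block (limma adjusted p = 0.106). Nor did it with extract as a random block, which does not pair the strains (limma adjusted p = 0.952). *argR*, earlier *ahrC*, the arginine regulator, differed by -0.07 ± 0.90 (SE).

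Over all 4094 genes and features tested, 5 changed between the strains, each at least 2-fold, and 173 had an unadjusted p under 0.05. Besides *gapB* and *pckA*, those that rose were *cotE*, for a protein that organises the spore coat, and *sacT*, for an antiterminator of sucrose use. *cotE* rose 10.8-fold (3.43 ± 0.34, SE; limma adjusted p = 0.01) and *sacT* 9.66-fold (3.27 ± 0.36, SE; limma adjusted p = 0.0161). Without background correction the values were 2.74 for *cotE* and 2.87 for *sacT*. *tcyP*, a cystine transporter gene, fell by 3.38 ± 0.33 (SE) on the log2 scale (limma adjusted p = 0.01). The mutant signal of *tcyP* was 1 to 3.4 times background, and without background correction its value was -1.81 (limma adjusted p = 0.114). The planned choice of genes to name fills each direction to 5 by unadjusted p, with the same direction in 3 of 3 extracts. It added 1 higher and 4 lower genes, which did not pass. They were *cotJA*, another spore coat gene, at 2.87 ± 0.41 (SE), the cold shock gene *cspB* at -4.49 ± 0.64, *dgcK* at -2.55 ± 0.35, *ycbP* at -2.38 ± 0.38 and *yaaC* at -2.06 ± 0.33. Without background correction *cotJA* lay at 2.09, *cspB* at -3.82, *dgcK* at -1.46, *ycbP* at -2.15 and *yaaC* at -1.58. The mutant signal of *dgcK* was 0.911 to 3.38 times background, so the size of its difference is uncertain. The count of 5 became 0 when any one of the 3 extracts was left out of both strains, in fits with 2 extracts per strain, while the log2 fold changes moved little. Over the fits with an extract left out of one strain or both they were 4.45 to 4.95 for *gapB* and 3.08 to 3.7 for *pckA*. They were 3.17 to 3.66 for *cotE*, 2.98 to 3.48 for *sacT* and -3.72 to -3.07 for *tcyP*. With extract as a block all 5 were called without each of the 3 extracts. Those blocked fits leave fewer residual degrees of freedom than the 2 of the full blocked fit, yet called more genes (106, 44 and 70 against 41). They therefore say little about how firm the 5 calls are. Without the block, the fits that left an extract out of both strains had 112, 201 and 99 genes at an unadjusted p under 0.05 without extracts 1, 2 and 3 in limma. With membrane set as a block of the 4 arrays the count was 28, in a fit that treats the arrays of extract 3 as separate samples. Within set A alone, which is extracts 1 and 2, the fit with extract as a block has the same limit of few degrees of freedom. It called 70 genes with all 5 among them, and the fit without the block called 0. With an extract left out of one strain and no block, the count was 6 without wild-type extract 2 and 5 without mutant extract 2. The count was 2 without wild-type extract 1, and 1 without wild-type extract 3, mutant extract 1 or mutant extract 3.

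Wild type and mutant of one experiment shared a day, and their deviations from the strain means correlated in each pair, so the fit was repeated with RNA extract as a block. It called 41 genes, 32 higher and 9 lower in the mutant, each at least 2-fold, and these included the 5 above. Among the 32 that rose with the block, 17 carry the names *cot*, *ssp* or *spo* of spore coat, small acid-soluble spore protein and sporulation genes, where 0.81 would be expected by chance (Fisher's exact test, one-sided, p = 8.26e-20). These name groups were chosen after the data were seen, and genes of one regulon are not independent. Within the block, *cotJC* rose by 3.62 ± 0.32 (SE), *cotJA* by 2.87 ± 0.22, *sspE* by 2.83 ± 0.35, *spoIIID* by 2.91 ± 0.40 and *spoIVA* by 2.27 ± 0.23. *cotJC*, *spoIIID* and *yhcT* were singled out after their values were seen. *cspB* (-4.49 ± 0.46), *dgcK* (-2.55 ± 0.30), *yhcT* (-2.25 ± 0.23), *ycbP* (-2.38 ± 0.30) and *yaaC* (-2.06 ± 0.28) fell, with the limit of low signal given above for *dgcK*, which lay at -1.46 without background correction. With a correction for array position, chosen after the data were seen, the blocked fit called 24 genes, 23 of them among the 41. Of the *cot*, *ssp* and *spo* genes, where 6, 5 and 6 rose with the block alone, 4, 1 and 4 rose with the correction. Not called there were *cotJC* (3.49 ± 0.41, SE; limma adjusted p = 0.0514), *sspE* (2.55 ± 0.35; 0.0759), *spoIVA* (2.31 ± 0.31; 0.0729), *dgcK* (-2.47 ± 0.30; 0.0526) and *ycbP* (-2.13 ± 0.30; 0.0768). With extract as a random block of the 4 arrays, which does not pair the strains, *sspE* (limma adjusted p = 0.0543), *yhcT* (0.0543) and *yaaC* (0.331) were not called. The fit with extract as a fixed block, without extract 1, 2 or 3, called 106, 44 and 70 genes on fewer residual degrees of freedom.

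**Figure D2:**
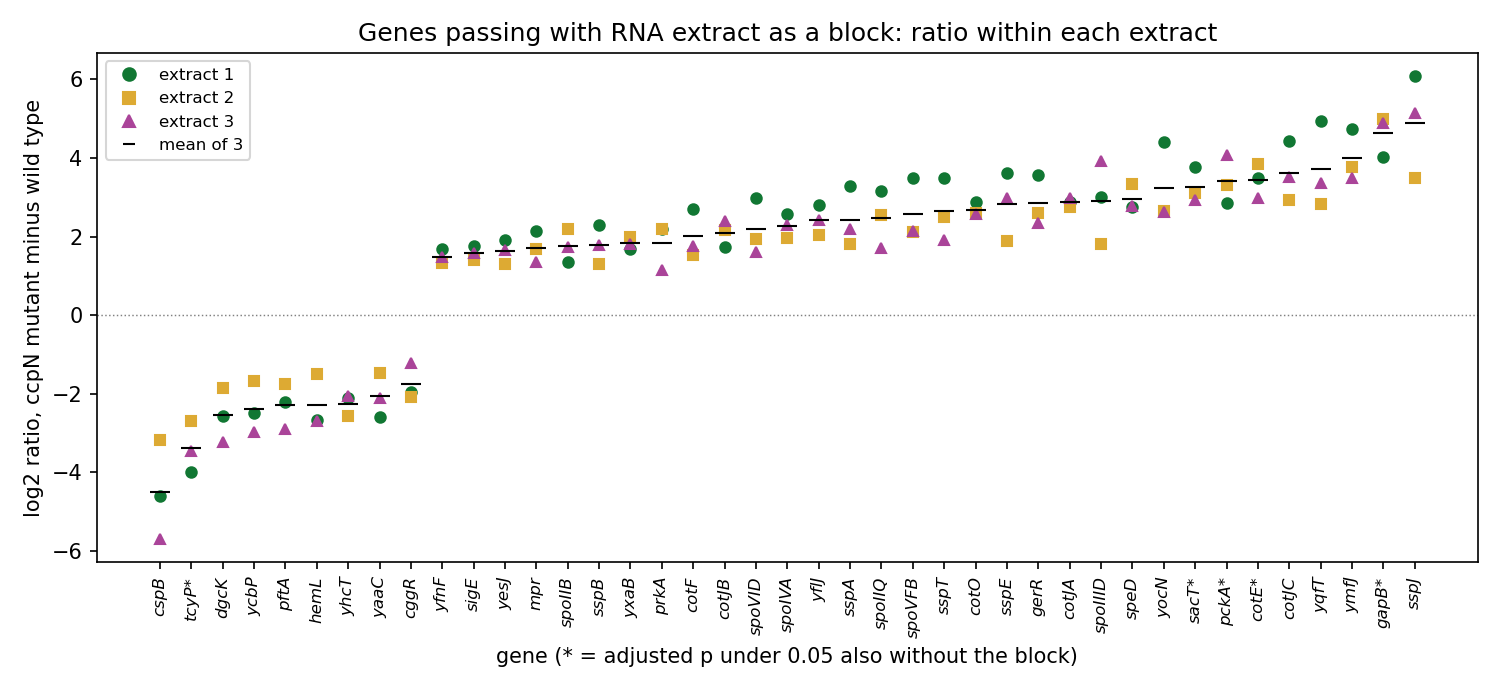
Log2 ratio of mutant to wild type (y axis) within RNA extracts 1, 2 and 3 for the 41 genes that passed with extract as a block (x axis, ordered by mean; a star marks the 5 that also passed without it). The 32 higher genes lie above 0 and the 9 lower genes below 0 in each extract, and extract 1 has the highest ratio for each of the 5 *ssp* genes.

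The list of sporulation and competence genes held members that were higher and members that were lower. Of the 47 measured, 1 rose (*cotE*) and none fell over all genes, and 9 rose and 1 fell when adjusted over the list alone. With the block 6 rose and none fell, and 11 rose and 10 fell when adjusted over the list alone. The spore genes *sspE* (2.83 ± 0.59, SE), *spoIVA* (2.27 ± 0.44) and *sigE* (1.57 ± 0.32), which encodes the early mother-cell sigma factor, were higher in 3 of 3 extracts and passed with the block (limma adjusted p = 0.0225, 0.0106 and 0.0335). Without it they did not pass (limma adjusted p = 0.226, 0.185 and 0.21). With extract as a random block of the 4 arrays, which does not pair the strains, the limma adjusted p was 0.0543, 0.0445 and 0.115, so that only *spoIVA* passed. With the position correction and the block none of the 3 passed (limma adjusted p = 0.0759, 0.0729 and 0.107). *comK*, the competence regulator, lay at -1.17 ± 0.33 (SE; limma adjusted p = 0.541). The list's median was -0.19 while its mean was 0.16 and its test pointed up, and it was not called (camera adjusted p = 0.312). The mixed test of fry, which asks whether members change in either direction and makes no comparison with other genes, passed for this list (adjusted p = 0.0142), the 1 list of 27 for which it did.

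Genes of overflow metabolism and acetoin use fell as a list, with a median log2 fold change of -0.4 over 15 measured members (camera adjusted p = 0.00212). Of these members 7 were lower in 3 of 3 extracts, against 23.5% of all genes. The median was -0.2 without background correction and ranged from -0.65 to -0.14 over the settings. The call was lost in the camera test with an estimated correlation (unadjusted p = 0.0171, adjusted p = 0.157). The estimate for this list was -0.004, below the preset 0.01, so correlation between its members does not account for the loss. The number of list calls by camera was also not particular to the real grouping. Of the 10 splits of the extracts into 3 and 3, 5, the real one included, gave at least its 4 list calls. Some of these splits put both strains of an extract on one side, so they carry differences between extracts. The 3 other splits that part each pair gave 2, 3 and 6 lists. This limit concerns the count of all 4 called lists, and does not show which lists the other splits called. No single member passed over all genes or adjusted over the list alone. *alsS* and *alsD*, which lead from pyruvate to acetoin, lay at -1.64 ± 0.41 and -1.13 ± 0.38 (SE, n = 3). With the block 2 members fell when adjusted over the list alone. The lactate dehydrogenase gene *lctE* lay at -2.62 ± 1.01 and the lactate permease gene *lctP* at -2.2 ± 1.04, but their ratios differed between extracts. For *lctE* they were 0.63, -3.51 and -4.96, and for *lctP* -0.2, -5.02 and -1.39.

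Genes of aromatic amino acid and histidine synthesis fell as a list, with a median of -0.39 over 22 measured members (camera adjusted p = 0.034; adjusted p = 0.563 with an estimated correlation). No member passed over all genes or adjusted over the list alone, and 9 were lower in 3 of 3 extracts, against 23.5% of all genes. *hisF*, *hisH* and *hisIE* of the histidine pathway lay at -1.03 ± 0.41, -0.88 ± 0.54 and -0.59 ± 0.34 (SE), and *trpB* of tryptophan synthase at -0.63 ± 0.35. With the position correction and the block, *hisF*, *hisH*, *hisIE* and *trpB* lay closer to no change, at -0.45, -0.22, -0.33 and -0.18. The median of the list was then -0.21, and the list was still called (camera adjusted p = 0.048). The list was no longer called without extract 2 in both strains (median -0.41, camera adjusted p = 0.071). Nor was it called without wild-type extract 2 (-0.29, camera adjusted p = 0.157), wild-type extract 3 (-0.34, camera adjusted p = 0.0759) or mutant extract 1 (-0.17, camera adjusted p = 0.406). With membrane set as a block its median was -0.27 (camera adjusted p = 0.0685). The limit that other splits of the extracts gave as many list calls holds here too.

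**Figure D3:**
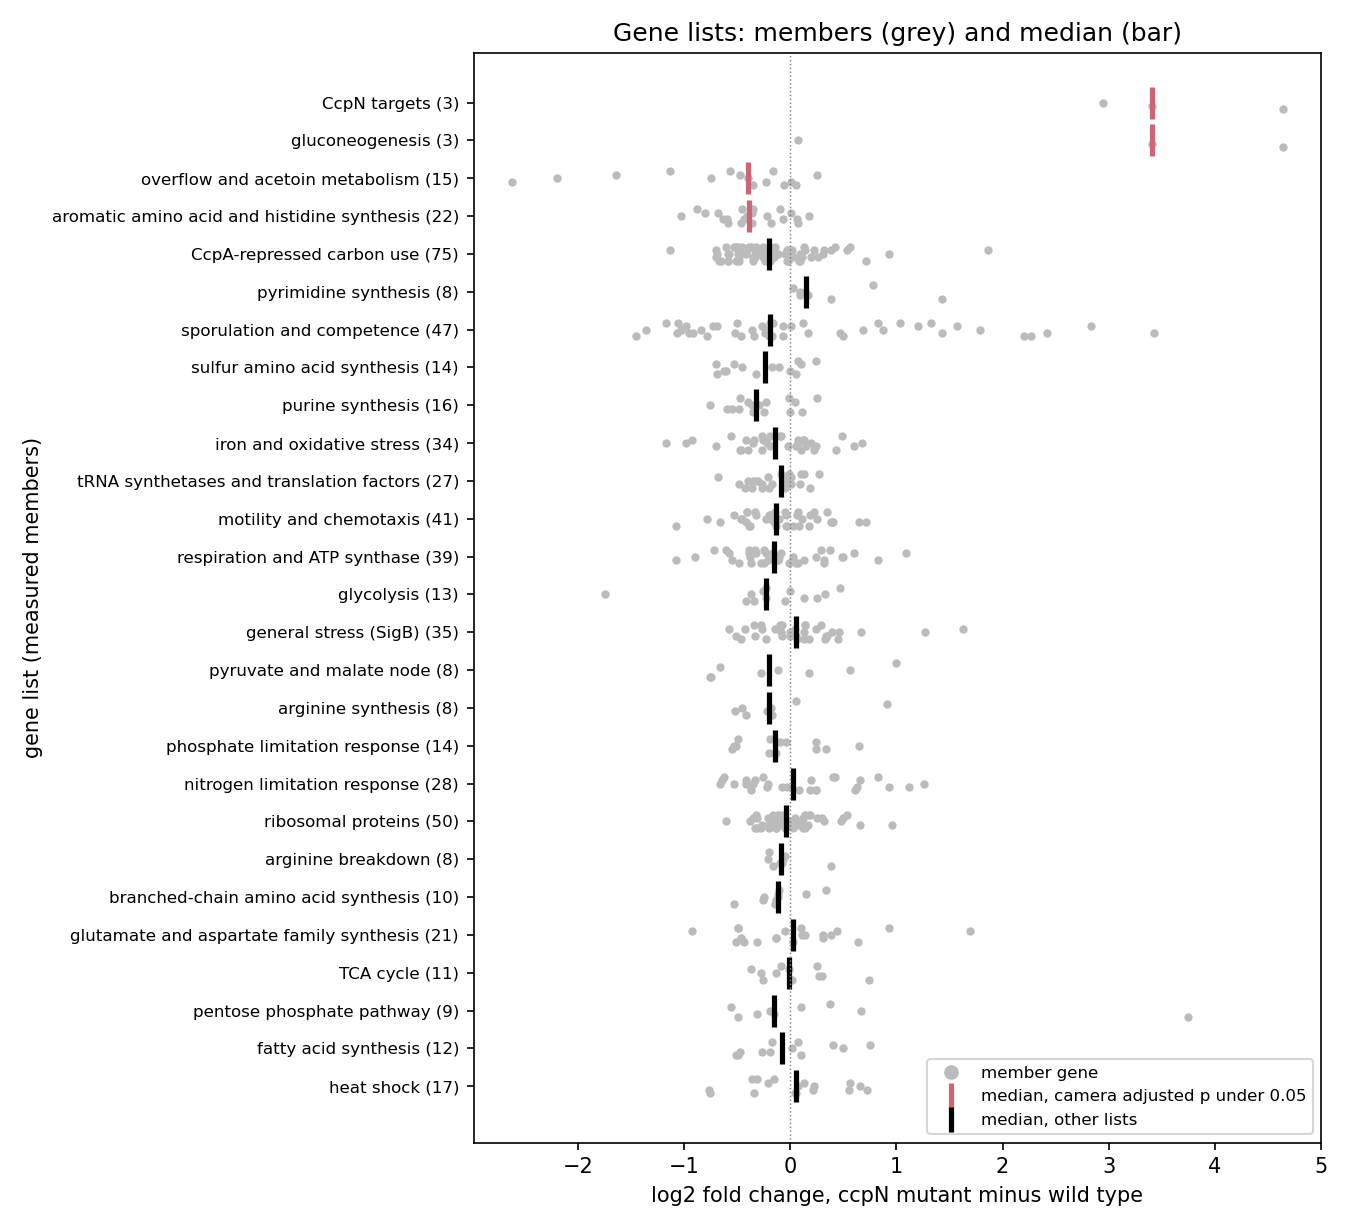
Log2 fold change, mutant minus wild type (x axis), of the members (grey points) and median (bars) of the 27 lists tested (y axis, number of measured members in brackets). Red bars mark the 4 lists called by camera, with medians of 3.41, 3.41, -0.4 and -0.39.

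Of the 27 lists tested, 23 were not called, glycolysis and sporulation and competence among them. The 75 measured genes of carbon use repressed by CcpA, the main regulator of carbon catabolite repression, had a median of -0.2 (camera adjusted p = 0.0663). This list was called in 9 of 29 settings, among them membrane set as a block (-0.22, camera adjusted p = 0.014). That fit treats the arrays of extract 3 as separate samples. All 9 settings use 4 arrays, take extract 3 from set C only, or leave out an extract. With extract as a block the list was not called (camera adjusted p = 0.0633). Central metabolism gave medians of -0.01 for the TCA cycle, -0.15 for the pentose phosphate pathway, -0.2 for the pyruvate and malate node and -0.15 for respiration and ATP synthase. In the pentose phosphate pathway *zwf*, for glucose-6-phosphate dehydrogenase, rose when adjusted over the list alone (3.75 ± 0.79, SE, with 6.37, 2.31 and 2.58 in the 3 extracts) and not over all genes (limma adjusted p = 0.226). It was singled out after its values were seen. Amino acid and nitrogen lists had medians of -0.09 (arginine breakdown), -0.2 (arginine synthesis), -0.12 (branched-chain synthesis), -0.24 (sulfur amino acids), 0.03 (glutamate and aspartate family) and 0.03 (nitrogen limitation). The nucleotide lists lay at -0.32 for purine and 0.15 for pyrimidine synthesis. Medians were -0.04 for ribosomal proteins, -0.09 for tRNA synthetases and translation factors, -0.08 for fatty acid synthesis and -0.13 for motility and chemotaxis. The stress lists lay at 0.05 for the SigB general stress response, 0.05 for heat shock, -0.14 for iron and oxidative stress and -0.14 for phosphate limitation. No member of these lists passed over all genes, *cotE* of sporulation and competence apart. Leaving out an extract brought in further lists. Without extract 1 in both strains these were carbon use repressed by CcpA (-0.21), pyrimidine synthesis (0.32), ribosomal proteins (0.18) and SigB general stress (-0.23, the opposite direction), with 8 lists called. Without mutant extract 3 they were sulfur amino acids (-0.48), purine synthesis (-0.65) and tRNA synthetases and translation factors (-0.3), with 7 called. Motility and chemotaxis was called without wild-type extract 1 (-0.26). Purine synthesis was also called without extract 2 in both strains (-0.6) and without wild-type extract 2 (-0.62). Pyrimidine synthesis was also called without wild-type extract 3 (0.42) and without mutant extract 1 (0.52). The *ccpN* operon list, with 2 genes, was too short to test as a list and had a median of -0.29.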

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

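The split counts were planned before the data were examined. In each set of 4 arrays of a strain, an array is reported when its gap to the nearest other array was large against the range. Of 62 such sets (27 named genes and 4 array measures in each strain), 6 had such an array, where chance gives about 1 in 20. Arrays 3 and 4 share an extract, which makes such gaps more common.

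In the wild type, *argR* reached 3.92 in array 2 against 0.87 to 1.24 in the others (the paired mutant array 2 was high as well, 3.49 against 0.9 to 1.45), *lctE* was 0.67 in array 1 against 3.94 to 4.38, and *lctP* was 3.54 in array 2 against -0.93 to -0.19. In the mutant, *sspE* was 5.77 in array 1 against 3.77 to 4.11. These are log2 levels relative to the median gene. The share of features under 2 times background was 6.5% in wild-type array 1 against 0.3% to 0.6%. The raw median of mutant array 2 was 127771 against 30416 to 40839, and that of wild-type array 2 was also the highest of its strain, at 89060.

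The 6 extracts of the strains can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 5 changed genes, and 1 of 10 splits, the real one, gave as many; the highest other count was 2. The same holds for genes changed at least 2-fold, with 5 in the real split and 2 as the highest other. For lists the real split gave 4 calls, and 5 of 10 splits gave as many. The highest other, 11, set wild-type extract 1 and mutant extracts 1 and 2 against the rest. Why it gave more was not tested. With extract as a block 4 lists were called. Like the real split, 3 others part each pair of extracts, and they gave 0 genes and 2, 3 and 6 lists. With the block, 4 sign patterns of the pairs exist, again too few. The real pattern gave 41 genes, 1 of the 4 gave as many, and the highest other gave 0.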

How the results depend on the processing

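The position correction and the block without each extract were chosen after the data were seen. Counts are of changed genes, the same at least 2-fold unless given. Against 5 genes, the count was 41 with the replicate block, 35 with 4 arrays and no block, 106 (100 at least 2-fold) with 4 arrays and experiment as a block, 17 with extract as a random block, 28 with membrane set as a block, 3 without normalization between arrays, 24 with position correction and block, and 106, 44 and 70 with the block and without extract 1, 2 or 3. The fits with 4 arrays and no block, experiment as a block or membrane set as a block treat the arrays of extract 3 as separate samples. Their counts of 35, 106 and 28 therefore rest on overstated replication. The random block takes account of the shared extract but does not pair the strains. Leaving out extracts without the block gave 0 to 6 genes and 4 to 8 lists, and with the block and without extract 1 it gave 8 lists. The cause was not tested. The other settings for genes gave 4 to 6. *gapB* passed in 25 of 28 settings, *pckA* and *cotE* in 20, *sacT* in 19 and *tcyP* in 17 of 27, and no named gene that passed changed direction. The settings reuse the same arrays and some overstate the replication, so these tallies do not measure how firm a call is.

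Of the 4 lists called, 0 passed with an estimated correlation (3 at an unadjusted p under 0.05) and 3 with fry. CcpN targets, gluconeogenesis and overflow metabolism passed in 28 of 29 settings and the aromatic and histidine list in 20. The SigB general stress list turned from 0.05 to -0.23 without extract 1, the lowest of -0.23 to 0.17 over the extracts left out (camera adjusted p = 0.0483; 0.0326 with the block), and its adjusted p ranged from 0.0326 to 0.993. The block changed no call of a list, and of named genes those given in the report. The random block was not run for lists. Without normalization the median of all genes was -0.34, against -0.08, so fold changes there are relative to that. *ccpN* ranged from -0.78 to -0.5 and *ppsR* from -0.38 to 0.41 when extracts were left out. Low signal limits extract 1, where 16.2% of mutant features lay under 2 times background and the log ratios had an SD of 0.97 against 0.61 in extract 2.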

Other observations

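The tests of the spore and run patterns were chosen after their results or related values were seen. Grouped by name after the data were seen, the 17 measured *ssp* genes had a median log2 fold change of 2.5, with medians of 3.5, 1.3 and 1.94 in extracts 1 to 3, and 15 were higher in 3 of 3 extracts. The 33 *cot* genes had a median of 0.94 (1.95, 0.25 and 0.76), and 19 were higher in 3 of 3. The 54 *spo* genes had a median of 0.26 (0.52, 0 and 0.26), with 20 higher and 5 lower in 3 of 3 extracts. The 23 *com* genes of competence, in contrast, had a median of -0.52 (-0.39, -0.74 and -0.55), with 13 lower and 1 higher in 3 of 3 extracts, and none passed on its own with or without the block. The 13 include the whole series *comGA* to *comGG* and are not independent. Of all genes, 23.5% were lower in 3 of 3 extracts, and the share higher in 3 of 3 is not given here. With an estimated correlation the unadjusted camera p was 0.0311 for *cot*, 0.0509 for *ssp*, 0.00836 for *spo* and 0.152 for *com*.

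The 50 *cot* and *ssp* genes together had a median of 1.47 in the mutant. Signal level as the source was argued against, since other genes of like mean level were not raised. In 10000 random lists of genes without *cot*, *ssp* or *spo* names, matched on mean level, the highest median was 0.16. That 0 of them had a median as high does not measure chance, because the group was chosen after the data were seen and its genes are not independent. Array position was argued against as the whole source, since the median after the position correction was 1.24 (SD over extracts 0.91), above the bound of 0.3 by little more than that SD. The correction takes in only features close in number, and log ratios of features 96 numbers apart also correlated, at 0.18. Of the 11 of these genes called with the block, 5 were called after the correction. Their median went from 2.68 to 2.62 and their median SE from 0.29 to 0.34. A single extract was argued against too, since the lowest of the medians per extract was 0.54. No biological explanation was tested, so an effect of the mutation and a difference in growth stage at harvest both stay open.

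From *cspB* to *yhcX*, 15 measured neighbours on the chromosome had a median log2 fold change of -1.58, and 13 were lower in 3 of 3 extracts against 23.5% of all genes. The size rests partly on low mutant signal, with a median under 2 times background for 4 of the 15. Without background correction the run's median was -0.77, with 13 lower in 3 of 3, and on the value table -0.63, with 12. With the block 4 of them, *cspB*, *tcyP*, *dgcK* and *yhcT*, fell, out of 9 genes that fell. Array position is argued against as the whole source by a median of -1.29 after the position correction (SD over extracts 0.21). That correction works by feature number and not by the layout of the membrane, and how much of the position effect it removed was not measured. The comparison with other windows decides nothing, since the run and its ends were chosen for low values: 0 of 253 windows had a median as far from 0. Loss of the whole segment is argued against by 3 of its genes, above the median gene on average in the wild type, with a ratio above -1 in each extract: *yhcJ* (-0.29 ± 0.32, SE), *yhcM* (-0.2 ± 0.33) and *yhcN* (-0.35 ± 0.38). Loss or silencing of part of the segment in the mutant strain was not tested, nor was whether signal from similar sequences could hide a loss.

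Log ratios of features 8 numbers apart correlated at 0.28 across features. Pairs of genes within 20 kb do not carry this, since without them the correlation was 0.27. Ratios between a pair of wild-type extracts, which hold no strain difference, showed it as well, with 0.21 as the lowest of 3, consistent with an effect of position on the membrane or in the spotting plate. No biological explanation was tested. Features are not independent replicates.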
